A study of Bos grunniens with 6 samples.

How the data were processed

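Cultured dermal papilla cells (3 libraries) and hair matrix cells (3 libraries) of yak skin were compared by small-RNA sequencing. Per the labels' protocols, both cell types were grown in DMEM/F12 with serum and growth factors, and libraries were made from 1 µg of total RNA with a TruSeq small RNA kit. The submitters' processing notes name Trimmomatic, HISAT2 2.2.1.0 and DESeq 1.20.0 without giving their roles, and the genome build, the miRNA reference and the rule for reads that match several entries are not given in the sources used here. The mRNA part of the study was not analysed here.

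The deposited table holds 2853 entries, 757 with cattle miRNA names and 2096 predicted ones, each with its sequence and a value per library. The values are called TPM by the authors and are RPM (reads scaled to a fixed library total), since in each library 100% of values are whole multiples of 1 step within a tolerance of 0.001 read. The steps give 23904796 to 24693655 reads per library, which are the total to which the deposited RPM values refer, and whole reads per entry were recovered from them. Listed entries hold 71.7% to 73.5% of these reads. All 6 columns of values were used.

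Entries with at least 1 RPM in at least 3 of the 6 libraries were tested, which left 503, of which 413 have cattle names. log2(RPM + 1) values were fitted with limma 3.58.1 (R 4.3.3) with cell type as the only term, moderated variances with a mean trend, and Benjamini-Hochberg adjustment over the 503. A miRNA was called at an adjusted p under 0.05 and at least 2-fold. Log2 changes are dermal papilla minus hair matrix, and fold values are ratios of mean RPM. The values were expected to be TPM when the design was fixed, and the test was kept because RPM are normalized values too.

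The 21 lists were fixed before the data were examined: the miR-200 family, other epithelial-enriched, mesenchyme-enriched, DLK1-DIO3 cluster, miR-17-92 and paralog clusters, let-7 family, miR-99/100/125 group, HOX-cluster miRNAs, miR-15/16/195/497 group, miR-29 family, miR-30 family, miR-23/27/24 clusters, miR-181 family, miR-221/222 cluster, miR-34 family, skin and hair follicle miRNAs, skeletal and cardiac muscle, blood and immune cells, endothelium, neural and melanocyte, and liver, gut and kidney epithelium. Lists with at least 4 tested members were tested with camera (preset correlation 0.01), adjusted over the lists, and again with an estimated correlation and with fry. Camera compares a list with the other miRNAs, and fry asks whether its members move, on balance, one way. Members were matched by name without the arm, so a list can hold both arms of a hairpin. Counts of called members refer to the tested entries of a list. Roles named for a list are background and may not hold for both arms.

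Named miRNAs were chosen by a rule fixed in advance. It takes the 10 called miRNAs with the largest log2 change in each direction among those with at least 100 RPM in the higher group and no overlap between groups, and the 5 most abundant miRNAs of each cell type. It adds 2 to 4 of the most abundant tested members of each list and every tested member of the miR-200, other epithelial and mesenchyme lists. Only miRNAs with cattle names are named, and any outside the rule is said to be chosen after its value was seen.

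Replicates were compared by a chi-square test on whole reads. The statistic per degree of freedom was 34.3 to 96.0, so no pair agreed within counting noise. This does not show that the libraries came from separate RNA, and all 6 were counted separately because the labels call them biological replicates. The median SD within a cell type was 0.118 on the log2 scale. Near-identical entries were those with at most 1 mismatch over at least 18 aligned bases. Reads of such entries could be divided by the authors' counting, so their values are uncertain.

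The limma step was tested on simulated data for this comparison, with 503 miRNAs of which 200 were changed. Calls were made for 2% of those changed 1.5-fold, 20% of those changed 2-fold, 92% of those changed 4-fold and 100% of those changed 16-fold, and for 0 of 303 unchanged ones, of which 2.64% had an adjusted p under 0.05. Of those changed 1.5-fold and 2-fold, 58% and 86% had an adjusted p under 0.05 in the right direction. Changes near 2-fold are therefore often left uncalled, mostly through the 2-fold minimum on the log2(RPM + 1) scale.

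Alternatives fixed in advance were pseudocounts of 0.5 and 10, no filter and a filter of 10 RPM, TMM scaling, median centring, quantile normalization, RPM recomputed without the 5 most abundant miRNAs, variances without trend, library weights, the replicate number as a block, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered whole reads, known miRNAs only, no fold minimum, and leaving out each library. Leaving out near-identical entries, and leaving out each library with the tested miRNAs held fixed, were added after the data were seen.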

Results

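Small RNA was sequenced from cultured cells of yak (Bos grunniens) skin. The cells were dermal papilla cells, the mesenchymal cells at the base of the hair follicle, and hair matrix cells, the proliferating epithelial cells that surround the papilla and form the hair shaft. Each cell type had 3 libraries, which the labels call biological replicates without naming animals or cultures. The comparison addresses which miRNAs differ in level between the cell types, as the series title states. Values are in RPM, the reads of an entry scaled to the library total, and each library rests on 23904796 to 24693655 reads, of which 71.7% to 73.5% fall on the listed entries. A floor of 3 reads lies at 0.121 to 0.125 RPM per library, and it covers counting error only. Between 427 and 441 of the 2853 entries reached 1 RPM in a library. Positions in the genome were not used here, so items are identified by miRNA name. The p-values measure the spread between these libraries.

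Dermal papilla and hair matrix cells had clearly separate miRNA profiles. All 40 tested members of the DLK1-DIO3 cluster, an imprinted cluster of miRNAs, were higher in dermal papilla cells. So were the mesenchymal miRNAs miR-143, miR-145, miR-199 and miR-214. In contrast, miR-140, from the same list of mesenchymal miRNAs, was higher in hair matrix cells. The miR-200 family, which represses the ZEB transcription factors and marks epithelial cells, and miR-183, miR-96, miR-182, miR-184 and miR-205 were higher in hair matrix cells. Of 503 miRNAs tested with limma, 227 were called, 127 higher in dermal papilla cells and 100 higher in hair matrix cells. On the log2(RPM + 1) scale, which understates the change of low miRNAs, 48 and 28 of these calls had a change of at least 3. In 226 of the 227 called miRNAs the libraries of the cell types did not overlap, against 423 of the 503 tested. Chance gives 10% for 3 against 3, but this rate does not hold for entries that reach 1 RPM in 1 cell type only. Without a dermal papilla library 62 calls fail the filter on low values, and without a hair matrix library 40 do. For calls that pass through 1 cell type only, the lack of overlap follows from the filter. The first principal component, which separated the cell types, held 97.3% of the variance. Log2 values of replicates correlated at 0.994 to 0.996, and those of libraries of different cell types at 0.767 to 0.778, across miRNAs, which are not independent replicates.

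miR-21-5p was the most abundant miRNA of both cell types, with 34.3% ± 0.994 (SD, n = 3) of listed reads in dermal papilla cells and 47.4% ± 0.553 (SD, n = 3) in hair matrix cells. Its log2 change of -0.46 ± 0.035 (SE) stayed under 2-fold (limma adjusted p = 9.85e-06). let-7i followed in dermal papilla cells with 15.8% ± 0.380 of listed reads, against 7.77% ± 0.139 in hair matrix cells, a log2 change of 1.03. That call was lost after median centring, at 0.75, and after quantile normalization, at 0.49. miR-143 and miR-148a took 8.49% ± 0.317 and 5.57% ± 0.261 of dermal papilla reads, and 0.124% ± 0.0130 and 0.609% ± 0.0307 of hair matrix reads. miR-184 was second in hair matrix cells, with 8.19% ± 0.213 against 0.0456% ± 0.00400 of listed reads in dermal papilla cells. miR-27b was among the 5 most abundant of both cell types, at 35522 ± 902 and 34797 ± 1823 RPM, a difference smaller than the replicate spread (log2 change 0.03, adjusted p = 0.535). Its near-identical relative miR-27a-3p was at 3448 ± 118 RPM in dermal papilla cells and 28034 ± 1266 RPM in hair matrix cells, 8.13-fold higher.

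**Figure D1:**
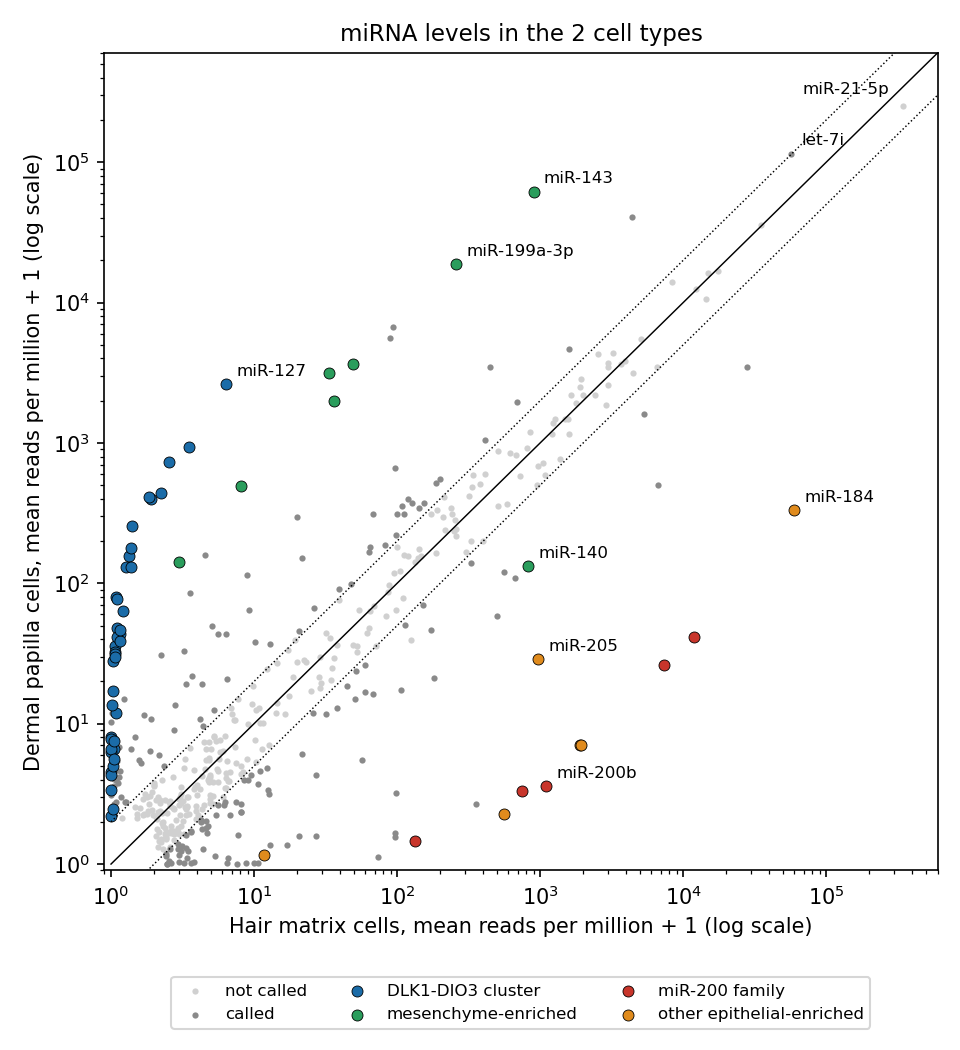
Mean RPM plus 1 of each tested miRNA in hair matrix cells (horizontal, log scale) and dermal papilla cells (vertical, log scale), n = 3 libraries each. The solid line marks equal levels and the dotted lines a 2-fold difference. All 40 tested DLK1-DIO3 members lie above the lines, and all 11 tested members of both epithelial lists lie below them.

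All 5 members of the miR-200 family were higher in hair matrix cells, with a median log2 change of -8.14 (limma camera adjusted p = 0.00303). The adjusted p was 0.395 with an estimated correlation. miR-200b was at 2.58 ± 0.677 RPM in dermal papilla cells and 1099 ± 62.7 RPM in hair matrix cells, a 426-fold difference. miR-200c, the most abundant member, was at 40.2 ± 4.36 and 11848 ± 226 RPM, and miR-200a at 25.2 ± 3.26 and 7362 ± 195.3 RPM. miR-429 and miR-141 were 327-fold and 290-fold higher in hair matrix cells. As a share of listed reads, the family made up 0.00975% ± 0.00126 in dermal papilla cells and 2.92% ± 0.0422 in hair matrix cells. The count of 5 was the same adjusted over the list alone.

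Each of the 6 tested members of the other epithelial list was also higher in hair matrix cells (median log2 change -7.73, camera adjusted p = 0.00237). The adjusted p was 0.397 with an estimated correlation, and 6 were called adjusted over the list alone. miR-183, miR-182 and miR-96, which are transcribed together, were 321-fold, 317-fold and 441-fold higher. miR-184, an abundant miRNA of the corneal epithelium, was at 331 ± 25.5 RPM in dermal papilla cells and 59426 ± 1342 RPM in hair matrix cells. miR-205, a miRNA of stratified epithelia, was at 27.7 ± 5.31 and 963 ± 29.1 RPM, a 34.8-fold difference. miR-375 was at 0.167 ± 0.111 and 10.8 ± 1.75 RPM. Among the largest changes in this direction was miR-11986b, outside the lists, at 1.69 ± 0.343 and 357 ± 33.2 RPM.

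All 40 tested members of the DLK1-DIO3 cluster were higher in dermal papilla cells (median log2 change 5.00, camera adjusted p = 1.46e-15), and the call held with an estimated correlation (adjusted p = 0.0411). The data held 54 entries of the cluster, and those under the filter on low values were not tested. Most of the 40 averaged under 1 RPM in hair matrix cells and passed the filter through the dermal papilla libraries. The direction of those members therefore follows from the filter, so the count of 40 and the list test are not independent of it. The count was 40 adjusted over the list alone. No read was found in any hair matrix library for 8 of the members, and with those at the floor of 3 reads over the group the median log2 ratio of mean RPM was 8.52. miR-127, read as TCGGATCCGTCTGAGCTTGGCT, was at 2619 ± 166 RPM in dermal papilla cells and 5.40 ± 0.482 RPM in hair matrix cells, a 485-fold difference. miR-379 and miR-411a, with 732 ± 23.2 and 941 ± 23.8 RPM in dermal papilla cells, were 477-fold and 376-fold higher. The other large changes were miR-493, miR-154c, miR-381, miR-370, miR-411c-5p, miR-369-3p and miR-382, with log2 changes of 7.83, 7.72, 7.64, 7.52, 7.04, 6.85 and 6.67. The cluster made up 0.974% ± 0.0380 of listed reads in dermal papilla cells and 0.00218% ± 0.000305 in hair matrix cells.

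Of the 8 tested mesenchyme-enriched miRNAs, 7 were higher in dermal papilla cells and 1, miR-140, was higher in hair matrix cells (median log2 change 6.03, camera adjusted p = 0.0166). With an estimated correlation the adjusted p was 0.397. Adjusted over the list alone, the counts were also 7 and 1. With a filter of 10 RPM the list was no longer called (adjusted p = 0.0777). miR-143 and miR-145, which share a transcript and are known from smooth muscle and fibroblasts, were 68.6-fold and 97.2-fold higher. miR-199a-3p was at 18880.3 ± 883 RPM in dermal papilla cells and 257 ± 23.96 RPM in hair matrix cells. miR-199a-5p, miR-199b, miR-199c and miR-214 had log2 changes of 5.80, 6.20, 5.60 and 5.95. miR-140, known from cartilage, was at 131 ± 9.83 RPM in dermal papilla cells and 823 ± 34.7 RPM in hair matrix cells.

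**Figure D2:**
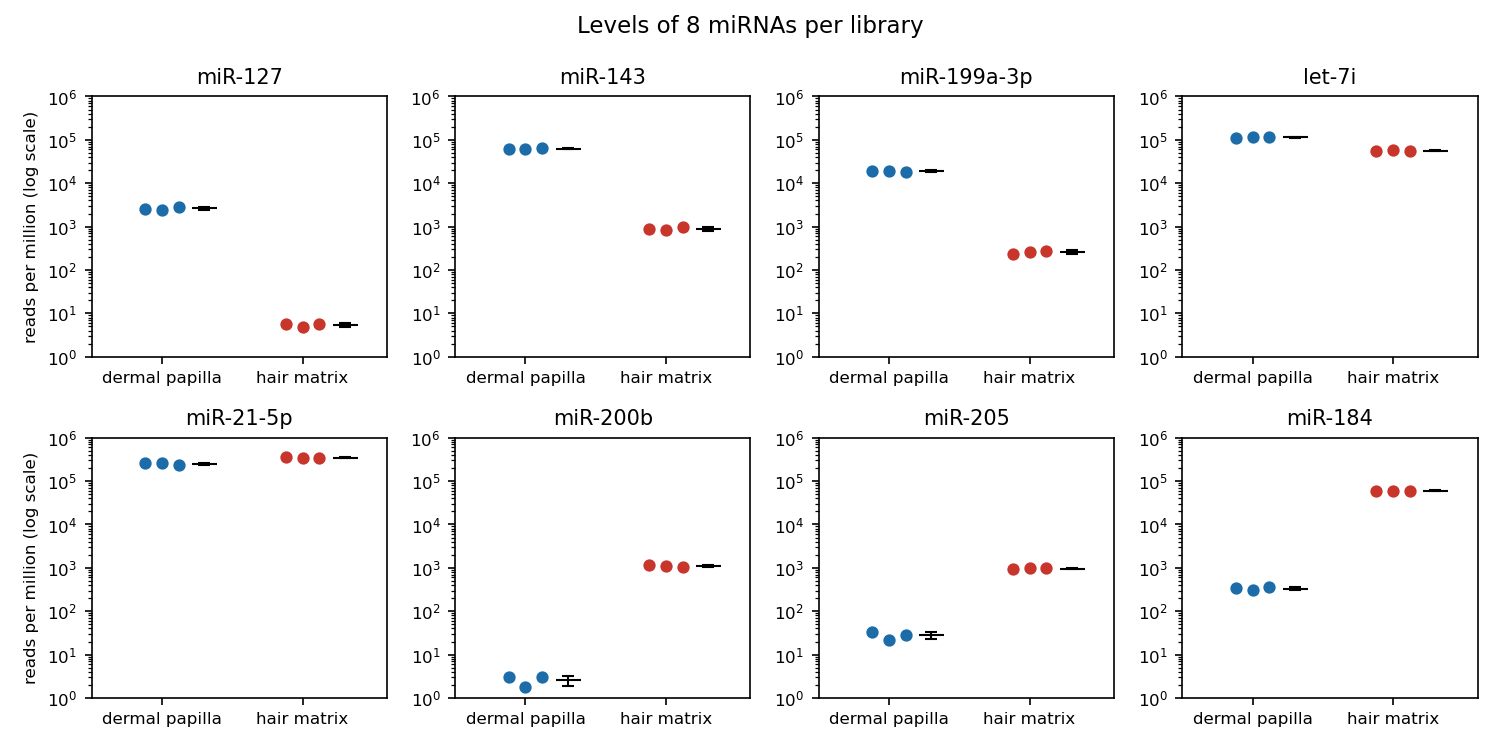
RPM of 8 miRNAs (log scale, the same axis in each panel) in the 3 dermal papilla libraries (blue) and the 3 hair matrix libraries (red), with the mean and SD as a bar beside the points. miR-127, miR-143 and miR-199a-3p are higher in each dermal papilla library, and miR-200b, miR-205 and miR-184 in each hair matrix library.

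The miR-15/miR-16/miR-195/miR-497 group, which is known to repress cyclins, had 5 of 10 members higher in dermal papilla cells and 5 not called (median log2 change 1.35, camera adjusted p = 0.0184). The adjusted p was 0.395 with an estimated correlation, 0.118 with a filter of 10 RPM and 0.0541 after quantile normalization. Without hair matrix replicate 1 it was 0.0558 and without hair matrix replicate 3 it was 0.0687. Adjusted over the list alone the count was also 5. The called members were low in abundance, and they include the -3p arms miR-424-3p and miR-503-3p, named after their values were seen. miR-195 and miR-497, chosen for naming after their values were seen, had log2 changes of 2.57 and 2.52. The abundant miR-16a, miR-15b and miR-16b had log2 changes of 0.56, 0.32 and 0.06 and were not called.

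Several families had no camera call. In the miR-17-92 and paralog clusters, known for promoting proliferation, 0 of 11 members were called with limma (adjusted p = 0.385 for the list). In limma 8 of them had a p under 0.05 both before and after adjustment, but changed less than 2-fold. edgeR and DESeq2 each called 1. miR-92a, miR-25 and miR-20a had log2 changes of -0.03, 0.56 and -0.53. In the let-7 family 1 of 10 members, let-7i, was called (list adjusted p = 0.852), and let-7f and let-7a-5p had log2 changes of -0.05 and 0.10. The miR-30 family had 0 of 7 members called with limma (list adjusted p = 0.927) and 0 with edgeR or DESeq2. Here 6 had a limma p under 0.05 both before and after adjustment, at less than 2-fold. The log2 changes were 0.45 for miR-30d, -0.06 for miR-30a-5p and -0.31 for miR-30e-5p. In the miR-99/miR-100/miR-125 group 2 of 5 members, miR-100 and miR-125b, were higher in dermal papilla cells, by 2.93-fold and 7.77-fold (list adjusted p = 0.408). The abundant miR-99a-5p, which is near-identical to miR-100, had a log2 change of -0.14.

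Among miRNAs of the HOX clusters, 3 of 5 were higher in dermal papilla cells and 1 was higher in hair matrix cells (list adjusted p = 0.431). miR-10b was at 6749 ± 140 RPM in dermal papilla cells and 92.4 ± 14.4 RPM in hair matrix cells, miR-10a at 657 ± 7.29 and 95.4 ± 0.446 RPM, and miR-615 at 7.96 ± 1.33 and 1.75 ± 0.153 RPM. The member higher in hair matrix cells was miR-196b, named after its value was seen, at 1.64 ± 0.357 and 5.19 ± 0.244 RPM. The miR-29 family, known to repress collagens, had 3 of 5 members higher in hair matrix cells (list adjusted p = 0.126). The 3 include the -5p arm miR-29d-5p, named after its value was seen. miR-29b was 4.41-fold and miR-29c 4.63-fold higher, whereas the abundant miR-29a had a log2 change of -0.20 and was not called. Both members of the miR-221/miR-222 cluster, which represses KIT, were higher in hair matrix cells, miR-221 by 3.29-fold and miR-222 by 8.70-fold, a list too short for a set test. The miR-34 family was split, with miR-34a 3.78-fold higher in hair matrix cells and miR-449a 11.98-fold and miR-449b 14.6-fold higher in dermal papilla cells (3 and 2 of 5 members higher in dermal papilla and hair matrix cells, list adjusted p = 0.83).

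In the miR-23/27/24 clusters, 1 of 8 members was higher in each direction, miR-27a-3p in hair matrix cells and miR-23b-5p, named after its value was seen, in dermal papilla cells (list adjusted p = 0.211). miR-23b-5p shares all its bases with the entry miR-10174-5p, also named after its value was seen, which was called in the other direction, and the sum of both entries was not called (log2 change -0.10, limma adjusted p = 0.24). miR-24-3p had a log2 change of -0.43 and was not called. The miR-181 family had 1 of 4 members called, miR-181d, higher in dermal papilla cells with a log2 change of 1.06 (list adjusted p = 0.133). This member was not called after median centring, at 0.78, after quantile normalization, at 0.77, or without the 5 most abundant miRNAs, at 0.87. miR-181a and miR-181b had log2 changes of 0.81 and 0.55. All 4 members had positive changes with a limma adjusted p under 0.05, but only miR-181d reached 2-fold. Without any 1 of the dermal papilla libraries the list was called, at adjusted p of 0.0336 to 0.0401, because fewer miRNAs passed the filter on low values.

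Of 18 tested entries of the skin and hair follicle list, 5 were higher in dermal papilla cells and 4 in hair matrix cells (camera adjusted p = 0.83). Its most abundant members were miR-21-5p, miR-148a and miR-24-3p. miR-148a was 9.15-fold higher in dermal papilla cells. miR-218 and miR-31, named after their values were seen, went in different directions. miR-218, known to act on Wnt signalling, was at 159 ± 2.08 RPM in dermal papilla cells and 3.52 ± 0.593 RPM in hair matrix cells. miR-31, known from the hair cycle, was at 16.4 ± 2.16 and 106 ± 1.43 RPM. The counts were 5 and 4 adjusted over the list alone, and for each of the other lists above the counts adjusted over the list alone equalled those over all miRNAs tested.

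Markers of other cell types were split, low or mostly not called. Entries under the filter on low values were not tested. In the muscle list, with 2 of 6 entries tested, miR-1 was 2.60-fold higher in dermal papilla cells. miR-499 was 42.9-fold higher in hair matrix cells, at 16.04 ± 1.74 RPM there. Of 9 blood and immune entries 4 were tested (list camera adjusted p = 0.623). Among these, miR-155 was 3.32-fold higher in dermal papilla cells, miR-146a was 6.13-fold higher in hair matrix cells, and miR-451 had a log2 change of 0.94. miR-451 was not called with limma on all libraries, but was called with DESeq2, at 1.07, and with limma without hair matrix replicate 3, at 1.06. The endothelial miR-126-3p was at 3.66 ± 0.392 and 2.81 ± 0.655 RPM and was not called, with an unadjusted p above 0.05 in limma and no call in edgeR or DESeq2. In the neural and melanocyte list, miR-128 was at 503 ± 3.46 RPM in dermal papilla cells and 6704 ± 153 RPM in hair matrix cells, and miR-204 at 83.7 ± 13.7 and 2.57 ± 0.197 RPM (list adjusted p = 0.927). miR-9-5p had a log2 change of 0.26. Of 9 entries of the liver, gut and kidney list 6 were tested (list camera adjusted p = 0.457). Among these, miR-215 was 2.72-fold higher in dermal papilla cells and 5 were not called. miR-215 was not called after median centring, at 0.98, or quantile normalization, at 0.87. miR-192 and miR-194 had log2 changes of -0.73 and -0.57, and quantile normalization made miR-192 a call, at -1.10.

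**Figure D3:**
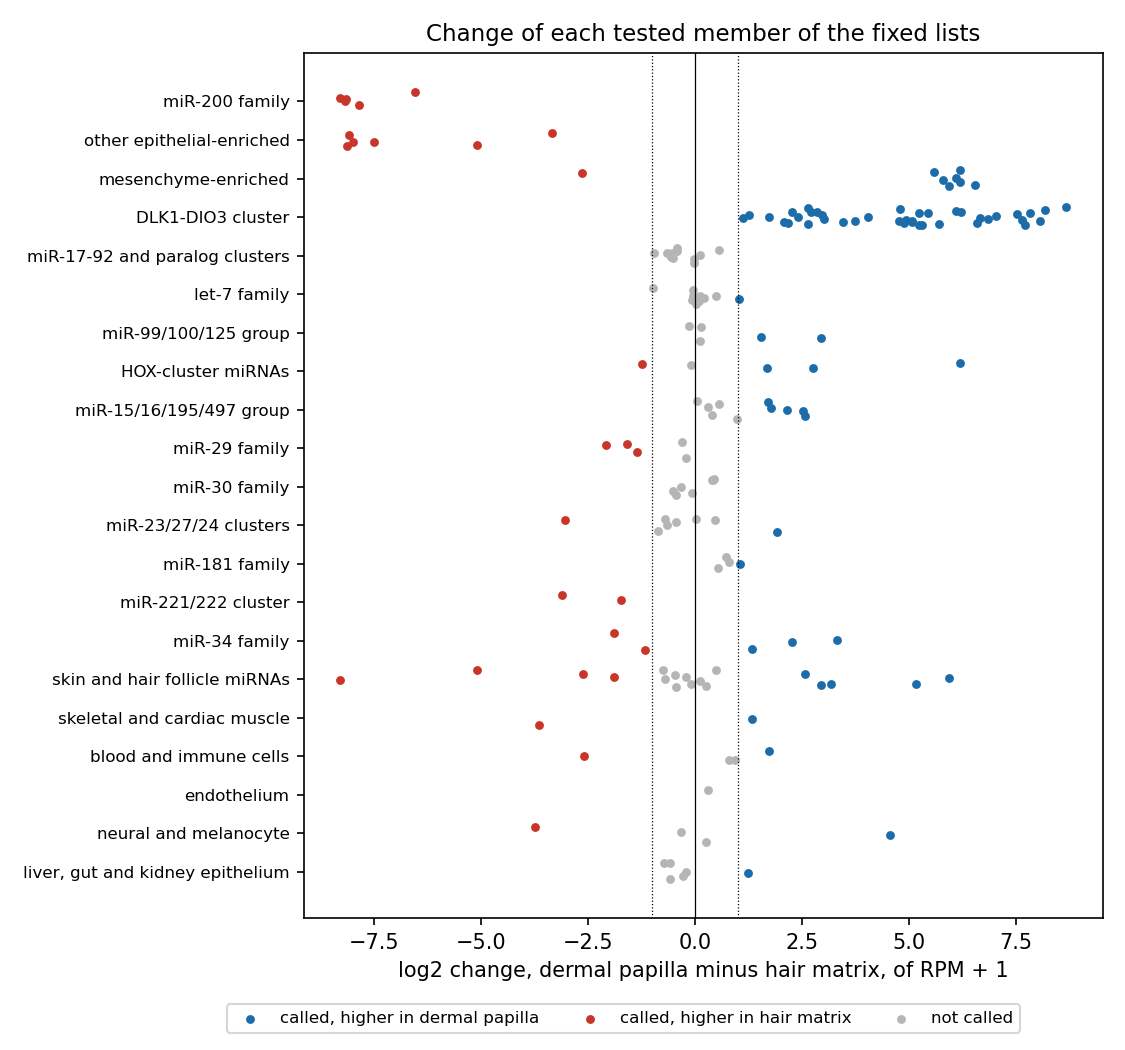
log2 change of RPM plus 1, dermal papilla minus hair matrix, of each tested member of the 21 lists fixed before the data were examined; blue and red points are called and grey points are not. The dotted lines mark the 2-fold minimum of a call, and a member of several lists appears in each.

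Calls required an adjusted p under 0.05 and at least 2-fold in limma on log2(RPM + 1). The split between directions depended on the scaling. The 127 and 100 calls became 109 and 137 after median centring of the same 503 miRNAs, but 127 and 103 after TMM scaling, where 504 entries were tested. When RPM were recomputed without the 5 most abundant miRNAs, 155 and 227 were called, but 764 entries then passed the filter, so the scaling and the set tested both changed. With a pseudocount of 10 the calls fell to 77 and 40, and miR-615, miR-29c, miR-181d, miR-449b and miR-215 were not called, and a filter of 10 RPM left 80 and 47 calls. Without any 1 of the dermal papilla libraries 65 calls were higher in dermal papilla cells, and without hair matrix replicate 1, 2 or 3 there were 64, 60 and 61 higher in hair matrix cells, because the filter on low values then removed miRNAs of 1 cell type. Median centring moved the median log2 change from -0.01 to -0.29. A further 189 miRNAs had an adjusted p under 0.05 at less than 2-fold, and 87 had a larger adjusted p.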

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

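Alternatives other than the count without near-identical entries and the runs with the tested miRNAs held fixed were chosen before the data were examined. No called miRNA of the 227 was called in the other direction under any alternative. Of 53 named calls, 47 held wherever they were tested; miR-615, miR-29c, miR-181d, miR-449b, miR-215 and let-7i were lost under at least 1.

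The total of 227 calls (127 higher in dermal papilla and 100 in hair matrix cells) became 117 (77 and 40) with a pseudocount of 10, 127 (80 and 47) with a filter of 10 RPM, which leaves 244 entries, 416 (212 and 204) with no fold minimum and 382 (155 and 227) without the 5 most abundant miRNAs, where 764 entries passed the filter. Quantile normalization gave 112 and 128. On whole reads edgeR called 284 (143 and 141) and DESeq2 286 (151 and 135), each with 226 of the 227. Without a library, 166 to 191 were called, 65 to 128 in dermal papilla cells and 60 to 104 in hair matrix cells. This comes from the filter, which 62 calls fail without a dermal papilla library and 40 without a hair matrix library. With the tested miRNAs held fixed, 226 to 231 were called. Without near-identical entries 184 were called.

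With an estimated correlation the adjusted p was 0.395 for the miR-200 family and the miR-15/miR-16/miR-195/miR-497 group and 0.397 for the other epithelial and the mesenchyme lists. A filter of 10 RPM gave 0.0777 for the mesenchyme list and 0.118 for the miR-15/miR-16/miR-195/miR-497 group, which had 0.0541 after quantile normalization, where the cause was not tested. Leaving out each library gave 0.00134 to 0.0687 for this group and 0.0336 to 0.205 for the miR-181 family, and 0.0134 to 0.0259 and 0.133 to 0.16 with the tested miRNAs held fixed. The filter of 10 RPM left 7 lists too short, leaving out a dermal papilla library 2, and DESeq2 gave no list test. With no filter, the HOX (0.0351), miR-29 (0.000334), miR-23/27/24 (0.00604) and miR-181 (0.000106) lists were called against many entries near 0. fry, which compares with no other miRNAs, called miR-17-92 (0.00743), let-7 (0.0184), miR-99/miR-100/miR-125 (8.81e-06), HOX (1.21e-06), miR-29 (8.8e-07), miR-23/27/24 (6.95e-05), miR-181 (8.81e-06), miR-34 (0.0426), skin and hair follicle (0.00589), blood (0.000283), neural (6.05e-05) and liver, gut and kidney (0.00589).

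Same-numbered libraries had correlations of deviations of 0.14, 0.08 and -0.27, against -0.43 to 0.39 for libraries of different numbers. The check gave no sign of pairing by number. With 3 libraries per cell type it cannot exclude a shared animal or batch. With the replicate block 228 were called, 127 and 101. Of the 10 splits of the libraries into 3 and 3, 1 gave as many calls in all and in each direction: the real split called 227, 127 and 100 with limma, and the highest other 0 each, with 418 and 5 at an unadjusted p under 0.05. With 10 splits the share cannot fall under 0.05.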

Other observations

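The tests of near-identical entries, of the mesenchymal miRNAs and of the epithelial miRNAs were chosen after their results or the values behind them were seen, except the parity test of read counts. The miRNAs named in this part that the naming rule did not take were also chosen after their values were seen. Outside the lists, miR-335 was among the miRNAs with the largest differences, at 0.652 ± 0.161 RPM in dermal papilla cells and 96.1 ± 2.64 RPM in hair matrix cells (SD, n = 3). miR-3604 was at 5621 ± 204 and 88.8 ± 11.7 RPM, and miR-149-5p at 295 ± 22.8 and 18.8 ± 2.56 RPM. miR-3120 went with miR-214, which lies on the opposite strand in other mammals, at 13.9 ± 1.03 and 0.233 ± 0.0966 RPM. miR-450a and miR-450b, which are clustered with miR-424 and miR-503, were at 309 ± 23.7 and 313 ± 32.1 RPM in dermal papilla cells and 99.4 ± 4.07 and 67.3 ± 2.85 RPM in hair matrix cells. The pair miR-224 and miR-452 had log2 changes of 1.48 and 1.19. In hair matrix cells miR-146b was at 181 ± 10.4 RPM, against 20.0 ± 1.96 RPM in dermal papilla cells. Of 90 predicted entries tested, 8 were higher in dermal papilla cells and 22 in hair matrix cells.

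Both arms of a hairpin come from 1 precursor, and the hypothesis that they change together was tested over 32 hairpins with both arms tested. The log2 changes of the arms had a Spearman correlation of 0.856 and a Pearson correlation of 0.88 across hairpins (permutation p = 1e-05 each, the smallest that 100000 resamples can give), where hairpins are not independent replicates. Both arms were called in 9 hairpins, with 0 in opposite directions, and the changes had the same sign in 26 of the 32. The 32 include miR-23b and miR-10174, whose reads may be divided between near-identical entries.

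Among miRNAs with a mean of at least 50 RPM in both cell types, some differed between replicates of 1 cell type, such as miR-107 (2.32-fold), miR-23b-3p (2.27-fold), let-7c (2.07-fold) and miR-16b (2.01-fold), and miR-378c, below that limit in dermal papilla cells and left out of the count, differed 4.84-fold. A candidate explanation is that reads were divided differently between near-identical entries, and above that limit 4 of the 5 entries that differed at least 1.5-fold had a partner, against 30 of 110 others (Fisher exact two-sided p = 0.0263). For miR-23b-3p, the range of the sum with its partners miR-10174-3p and miR-23a was 0.412 times that of the entry alone in hair matrix cells. In dermal papilla cells it was 0.670 times, too weak a drop to decide. With miR-10174-3p alone, which differs by 1 base in length and otherwise shares the sequence, the sum varied less than either entry. Its SD in dermal papilla cells was 146 RPM, against 321 RPM for miR-23b-3p and 382 RPM for miR-10174-3p. Its replicates differed at most 1.07-fold in either cell type. The sum of miR-23b-5p and miR-10174-5p had a log2 change of -0.10 between the cell types. A pair of predicted entries that differ by 1 base in length had a sum within 1.05-fold between replicates. That explanation stays open for let-7c and miR-16b, whose sums varied over a wider range of RPM than the entries alone, and for miR-107, whose sum varied over 0.698 times the range of the entry in hair matrix cells and 4.54 times in dermal papilla cells. Counting the same reads 2 times is argued against by 4 odd read counts among the 6 library values of let-7c and miR-23b-3p at the high level; no biological explanation was tested.

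The 7 mesenchyme-enriched miRNAs that were higher in dermal papilla cells were seen in the hair matrix libraries at 1.03% to 1.76% of their dermal papilla level, while miR-140, left out of the test, was at 629%. Carry-over of dermal papilla RNA or reads is argued against as the whole source, because the 11 DLK1-DIO3 members of at least 100 RPM sat at 0.155% to 0.283%, and the medians differed 6.64 times. A share of another mesenchymal cell type in the hair matrix cultures, one without DLK1-DIO3 miRNAs, and low expression in hair matrix cells themselves cannot be told apart, since the 7 members kept a similar ratio (highest over lowest 1.71) that both allow. miR-143, the most abundant member, was at 898 ± 88.2 RPM there.

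Epithelial miRNAs were seen in the dermal papilla libraries at low levels. The miR-200 family and miR-183, miR-96 and miR-182 sat at 0.227% to 0.345% of their hair matrix level (highest over lowest 1.52). Carry-over of hair matrix RNA, reads or cells and low expression in dermal papilla cells both allow such a ratio and cannot be told apart. miR-184 and miR-205 sat higher, at 0.557% and 2.88%, with miR-184 at 1.62 times the highest of the others, and both above it in each dermal papilla library. miR-375, left out of the test, was at 1.55%, from 12 reads over the dermal papilla libraries. Carry-over alone is argued against for miR-205. For miR-184 it stays undecided, because 1.62 times is close to the 1.52 by which the other members differ among themselves. Expression in dermal papilla cells stays open as a hypothesis, and other sources were not tested.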
